A study of Homo sapiens with 18 samples.

How the data were processed

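MAX was profiled by chromatin immunoprecipitation and sequencing with a mouse reference genome added (ChIP-Rx) in U2OS cells with inducible WT, 3A or 7A MYC. Per the labels, each of the 6 combinations of MYC form and Dox had 2 immunoprecipitation libraries and 1 input. The antibody field names MAX, while the protocol text of the same samples describes an anti-FLAG antibody; the antibody field and titles were followed here. Cutadapt, Bowtie2, SAMtools, Picard and MACS2 and the builds hg19, hg38 and mm10 are named per the submitters' processing notes, without versions or roles. The authors deposited 1 peak list per MYC form. Whether peaks were called on pooled replicates, with input or no Dox libraries as control, or with the mouse reads used for scaling, is not given in the sources used here. Peak names carry both a plus and a minus sign, each list holds no overlapping peaks, and nothing in it separates Dox from no Dox, so that this comparison was not analysed here.

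The lists have no header and follow the narrowPeak layout. The score of a peak, as deposited, was 10 times its −log10 q, rounded down, in over 99% of peaks (99.6% in WT, 99.8% in 3A and 99.6% in 7A). The fold enrichment in the deposited lists is the peak caller's linear ratio at the summit. The authors' −log10 p and −log10 q stand beside it, and the lowest −log10 q was 5.15 in WT, 5.04 in 3A and 5.69 in 7A. All positions were read as hg38, since contig names and peak ends matched that build, and are printed counting from 1. Columns of other samples numbered 0.

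Peaks were compared by overlap of at least 1 bp. Shares have 95% Clopper-Pearson intervals, which cover counting error only. The gene table used (RefSeq, GRCh38.p14) gives the outer ends of genes without strand or exons, so the planned promoter measure became a summit within 1000 bp of either end of a protein-coding gene on chromosomes 1 to 22 and X. The planned count of E-box motifs needs a genome sequence and was not analysed here. For 20 gene lists, members with such a peak were set against all other protein-coding genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the lists within each peak list and a threshold of 0.05. Every member was matched to the gene table. The lists are MYC target genes of growth, MAX network, cytosolic and mitochondrial ribosomal proteins, RNA polymerase I and ribosome assembly, nucleotide and one-carbon synthesis, glycolysis and lactate transport, polyamine and methionine cycle, cytosolic aminoacyl-tRNA synthetases, translation factors, RNA polymerase III, MYC cofactors, cell cycle and replication, p53 target genes, immediate early genes, unfolded protein and amino acid stress, lysosome and autophagy, circadian clock, germline genes of MGA and E2F6, and lineage genes of other tissues. The share of genes with a WT gene-end peak that also had a gene-end peak in a mutant list was taken per gene list. It was placed among 10000 random gene sets of equal size, matched in 10 bins of WT fold enrichment. That percentile is a description of these lists.

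Gene lists, tests, thresholds and the rule for named genes were fixed before the data were examined; the gene-end measure, ranks across lists and recovered coverages were chosen afterwards. Named are, of each gene list, up to 4 members with the strongest WT peak and up to 4 with a peak in WT alone, and all members of the MAX network. Named besides are the 10 strongest gene-end peaks of each list, the 10 strongest WT ones with no mutant partner, the 5 strongest of each mutant with no WT partner, and the 5 strongest WT peaks overlapped in 1 mutant list and not the other. Some items that this rule names are not reported here.

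From the deposited fold enrichment and −log10 p, the coverage of treatment and background at each summit was solved with the formulas of MACS2, for 95.7% of WT, 97.1% of 3A and 93.0% of 7A peaks. On 5000 simulated summits 97% were solved, and 100% of those gave the right values. On simulated gene lists the enrichment step called 5 of 5 changed lists and 1 of 15 unchanged ones. Of 40 unchanged random sets, 1 lay in the outer percentiles. Alternatives were a −log10 q of at least 10, joining within 100 bp, an overlap of 50% of both peaks, summits within 100 bp, lists of equal length, the strongest 5000 peaks, windows of 500 and 2500 bp, whole gene bodies, and a background of genes with a peak within 10000 bp. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.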

Results

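The series measured where MAX, the DNA-binding partner of MYC, sits on the genome of U2OS cells, a human osteosarcoma line. The cells lacked their own MYC and carried a doxycycline-inducible copy of wild-type MYC (WT) or of a mutant named 3A or 7A in the labels. Dox (doxycycline) was given at 1 µg/ml over 24 h or left out, and 10% mouse NIH3T3 cells were mixed in as a reference genome. The labels describe 18 libraries: 12 MAX immunoprecipitations, in 6 groups of 2 biological replicates, and 6 inputs. The data analysed here are 3 peak lists, 1 per MYC form. No list separates Dox from no Dox or replicate from replicate, so each value below describes 1 list, has no replicate check, and is no test of a difference between MYC forms. The depth of the libraries is not given in the lists.

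The first comparison asked how many MAX sites each MYC form came with. The WT list held 34622 peaks, the 3A list 27294 and the 7A list 25159. These peaks covered 24.9 Mb, 19.2 Mb and 19.96 Mb, with median widths of 552 bp, 578 bp and 672 bp. The strongest WT gene-end peak lay at ZNF131, a zinc-finger gene (hg38, chromosome 5, 43120518 to 43121968), with a fold enrichment of 246.0. PTPRS followed at 212.5, then a peak shared by HSF2BP and RRP1B at 207.9, DHX33 at 186.2 and NCL, which encodes nucleolin, at 177.7. SLC33A2, DIAPH1, KCNQ5, the pair ANKMY1 and DUSP28, and NABP1 completed the strongest 10, down to 158.7. In the 3A list the strongest gene-end peaks were those of PGK1, a glycolytic enzyme, at 311.3 and UTP11 at 269.9, followed by FMNL3, DHX33, DHDDS, ATL3, ZFYVE27, the pair CCDC47 and DDX42, the pair HSF2BP and RRP1B, and WIPI1. In the 7A list they were those of C17orf100 and MED31 at 347.1 and ZFYVE27 at 265.4, followed by RNF130, FMNL3, the pair C16orf96 and CDIP1, MLLT1, UTP11, the pair LACTB2 and XKR9, ZFR and SPOP. The fold enrichment and the −log10 q of a peak are the authors' own values, and they describe or rank peaks within their list.

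The second comparison asked whether the mutant lists held the same sites. Nearly all mutant peaks lay on WT peaks: 95.4% of the 3A peaks (95% interval 95.2 to 95.7, n = 27294) and 96.6% of the 7A peaks (96.4 to 96.8, n = 25159) shared at least 1 bp with a WT peak. In the other direction, 74.0% of the WT peaks (73.6 to 74.5, n = 34622) were overlapped by a 3A peak and 69.9% (69.4 to 70.4) by a 7A peak. The WT list is the longest, and lists of unlike length cannot cover each other equally. With all lists reduced to the length of the shortest, these shares of WT peaks were 82.6% and 81.9%. The shares of mutant peaks on WT peaks then lay outside the intervals given above. Neither mutant list overlapped 7943 WT peaks, or 22.9% (22.5 to 23.4). The mutant lists overlapped each other for 87.8% of the 3A peaks (87.4 to 88.2) and 94.3% of the 7A peaks (94.0 to 94.6). Merged over the lists, the peaks formed 36039 regions, of which 23007 had a peak in all 3 lists, 2452 in WT and 3A, 986 in WT and 7A and 439 in 3A and 7A. Peaks of a single list made up 7943 regions for WT, 801 for 3A and 411 for 7A.

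**Figure D1:**
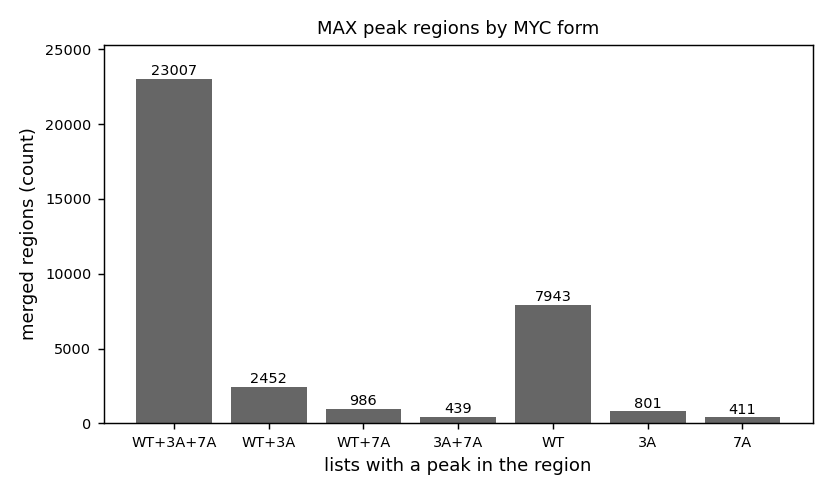
Number of merged peak regions (vertical axis, count) by the lists that hold a peak there (horizontal axis). Regions with a peak in all 3 lists number 23007, and regions of the WT list alone number 7943.

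WT peaks with no mutant partner were mostly the weaker and narrower ones. Their median fold enrichment was 7.54 and their median width 323 bp, against 13.4 and 744 bp for WT peaks overlapped in both mutant lists. The share of WT peaks overlapped by a 3A peak went from 51.3% (49.7 to 53.02) in the weakest 10% of the WT list to 98.1% (97.6 to 98.5) in the strongest, and for 7A from 44.8% (43.1 to 46.5) to 97.55% (97.0 to 98.0). Some strong gene-end peaks were still without a partner, led by PHB2, a prohibitin gene (chromosome 12, 6965094 to 6965486), at a fold enrichment of 43.2. LOC124901225, XPNPEP2, the pair JMJD8 and STUB1, FTL, which encodes ferritin light chain, ACTL8, CAMKV, TMEM255B, CD151 and the pair PEG3 and ZIM2 followed, down to 29.4. With all lists reduced to the length of the shortest, the WT share without a partner was 13.6%. Among the strongest 5000 peaks of each list by −log10 q it was 20.9%. There a WT peak also counted as without a partner where its mutant partner ranked below 5000 in its own list. That value is thus no share of strong WT peaks absent from the full mutant lists.

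**Figure D2:**
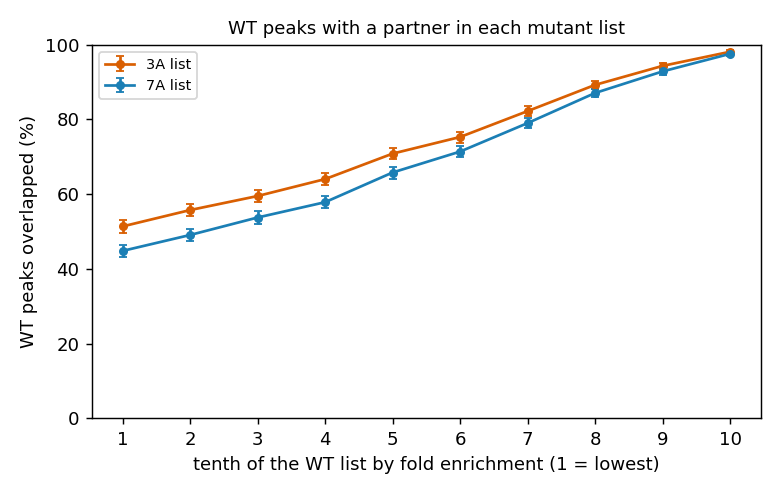
Share of WT peaks overlapped by a 3A or a 7A peak (vertical axis, %) in each of 10 equal parts of the WT list by fold enrichment (horizontal axis, 1 is the lowest); bars are 95% Clopper-Pearson intervals. The share is 51.3% for 3A and 44.8% for 7A in the weakest part and above 97.0% for both in the strongest.

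Peaks found in a mutant list and not in WT were few and weak: 1254 in 3A and 855 in 7A, with median fold enrichments of 6.91 and 7.11. The strongest at gene ends were NSG2 (25.3), ZBTB7B, LOC105370092, NR1D1, a circadian repressor, and ADAMTS9 in 3A, and TDRD9 (19.5), SCHIP1, PAK6, CIC and SGSM2 in 7A. Among the WT peaks overlapped in 3A and not in 7A (2479), the strongest lay on chromosome 12 at 30844495 to 30844838, away from any protein-coding gene end, at 67.7, and the strongest 5 included 1 gene-end peak, at ZNF580 (49.0). Among those overlapped in 7A and not in 3A (1042), the strongest was at ZCCHC7 (chromosome 9, 37119844 to 37120517) at 77.3, followed by EPHA8 at 63.6, and AGAP3 was the fifth at 37.6. Counting summits up to 2500 bp from a gene end, CAMKV, TMEM255B, ADAMTS9, NR1D1, SGSM2 and AGAP3 had a peak in all 3 lists.

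The third comparison asked where the peaks lay relative to genes. Summits lay within 1000 bp of an outer end of a protein-coding gene for 31.1% of the WT peaks (30.6 to 31.6, n = 34617), 37.7% of the 3A peaks (37.1 to 38.2, n = 27291) and 39.6% of the 7A peaks (39.0 to 40.2, n = 25157). Positions 20000 bp to either side of the same summits gave 4.65%, 5.0% and 5.14%. WT peaks overlapped in both mutant lists were at gene ends in 41.4% of cases (40.7 to 42.0) and those overlapped in neither in 8.64% (8.03 to 9.28). Of the latter, 49.0% (47.9 to 50.1) lay outside protein-coding genes, against 29.3% (28.7 to 29.9) of the former. The gap was also present among peaks of like fold enrichment: between 10 and 15 the gene-end shares were 40.6% (39.3 to 42.0) and 7.93% (6.62 to 9.40). Coverage and width were not matched. Over all fold enrichments the median treatment coverage was 192.1 for peaks overlapped in both and 75.2 for those overlapped in neither. The median background was 14.0 and 9.0. A gene end can be the start or the end of transcription or that of a neighbouring gene, since strand was not used here.

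The fourth comparison asked which gene groups carried MAX peaks at their ends. In the WT list 11471 of 19974 protein-coding genes did (57.4%), in 3A 11088 (55.5%) and in 7A 10934 (54.7%), and 10575 did in all 3. Genes of protein synthesis had peaks more often than other genes. In the WT list, 41 of 43 translation factors had a peak (Fisher's exact test, 2-sided, odds ratio 15.2, adjusted p = 9.05e-08), as did 49 of 52 genes of RNA polymerase I and ribosome assembly (odds ratio 12.2, exact adjusted p = 1.64e-08), 72 of 78 cytosolic ribosomal protein genes (odds ratio 8.95, exact adjusted p = 2.46e-10), 68 of 76 mitochondrial ribosomal protein genes (odds ratio 6.33, exact adjusted p = 9.44e-09) and 20 of 21 RNA polymerase III genes (odds ratio 14.8, exact adjusted p = 0.000452). Of the MYC target genes of growth 52 of 56 had a peak (odds ratio 9.68, exact adjusted p = 2.08e-08). In 3A the same groups had 41, 49, 73, 68, 19 and 52 members with a peak, and in 7A 41, 49, 72, 68, 19 and 51. Each of these passed the same exact test, with the largest adjusted p, for RNA polymerase III, at 0.00154 in 3A and 0.00134 in 7A. With genes that had a peak within 10000 bp as the background, RNA polymerase III did not pass in 3A (exact adjusted p = 0.0713) or 7A (exact adjusted p = 0.0626).

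The strongest members of these groups had peaks in all 3 lists. Among ribosome assembly genes, NCL had fold enrichments of 177.7 in WT, 79.1 in 3A and 69.9 in 7A, each on the scale of its own list, followed in WT by NOP58 (133.9), DKC1 (132.4) and RPF2 (90.4). The leading MYC targets in WT were CBX3 (145.5), NOP56 (121.6), HK2 (115.9) and DUSP2 (112.9). Among the leading ribosomal protein genes were RPL14 (113.2), RPL5 (100.6) and RPSA (98.6), and the leading mitochondrial ones were MRPL3 (123.4), MRPL43 (77.3), MRPL15 (73.7) and MRPL20 (48.5). Among translation factors PABPC1 (133.9), EEF1B2 (132.0), EIF4H (103.97) and EIF3E (94.6) led, and among RNA polymerase III genes GTF3A (89.8), POLR3D (84.5), GTF3C4 (70.4) and POLR3G (67.3).

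Most genes of metabolism, division and stress also had a WT peak. In WT a peak was found at 25 of 29 genes of nucleotide and one-carbon synthesis (odds ratio 4.64, exact adjusted p = 0.00239), led by MTHFD1L (140.7), ATIC, NME1 and PPAT, and at 20 of 23 cytosolic aminoacyl-tRNA synthetase genes (odds ratio 4.95, exact adjusted p = 0.00808), with IARS1 (99.4), FARSB and GARS1 among the strongest. Cell cycle and replication had 33 of 36 (odds ratio 8.17, exact adjusted p = 2.99e-05), led by CCNE2 (87.7), CDK6, MCM7 and MCM4. Lysosome and autophagy had 35 of 39 (odds ratio 6.50, exact adjusted p = 3.57e-05), led by GUSB (85.7), WIPI1, LAMP1 and CTSF, and unfolded protein and amino acid stress 21 of 25 (odds ratio 3.90, exact adjusted p = 0.0115), led by PDIA4 (73.9), ATF5, SLC3A2 and DNAJB9. MYC cofactors had 20 of 23 (odds ratio 4.95, exact adjusted p = 0.00808), led by TOP1 (48.1), KAT5, EP400 and HCFC1. Glycolysis and lactate transport had 16 of 21 (odds ratio 2.37, exact adjusted p = 0.134), led by HK2, SLC16A1 (106.6), LDHA (100.3) and ENO1 (85.5), and the polyamine and methionine cycle 10 of 12 (odds ratio 3.71, exact adjusted p = 0.0980), led by ODC1 (112.9), SRM, MAT2A and MTAP; neither passed the test in any list. With lists of equal length both passed in WT (exact adjusted p = 0.0334 and 0.0443), and with a window of 2500 bp glycolysis passed in WT, 3A and 7A (exact adjusted p = 0.0125, 0.00902 and 0.000893). With whole gene bodies in place of gene ends, glycolysis (exact adjusted p = 0.0109, 0.00641 and 0.00333) and the polyamine cycle (exact adjusted p = 0.0260, 0.0141 and 0.0150) passed in WT, 3A and 7A. The circadian clock, with 12 of 18 (odds ratio 1.48, exact adjusted p = 0.483) and NR1D2 (75.4), DBP, TEF and CRY1 in front, did not pass either, but did in all 3 lists with 2500 bp (exact adjusted p = 0.00727, 0.0184 and 0.0165) and in WT with whole gene bodies (exact adjusted p = 0.00295). The p53 target genes had 20 of 25 in WT (odds ratio 2.97, exact adjusted p = 0.0313), led by BAX (68.3), MDM2, PLK3 and POLH, and did not pass in 3A (18 of 25, exact adjusted p = 0.137) or 7A (19 of 25, exact adjusted p = 0.0569); the difference between lists was not tested. With 2500 bp they passed in all 3 (exact adjusted p = 0.00489, 0.00902 and 0.00119), as with whole gene bodies (exact adjusted p = 0.00301, 0.000985 and 0.000873). With genes that had a peak within 10000 bp as the background, 7 groups in place of 14 were enriched in the WT list. The calls that ended there were those of nucleotide synthesis (exact adjusted p = 0.465), aminoacyl-tRNA synthetases (0.116), MYC cofactors (0.313), cell cycle (0.0901), unfolded protein stress (0.313), p53 targets (0.499) and the MAX network (0.429).

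**Figure D3:**
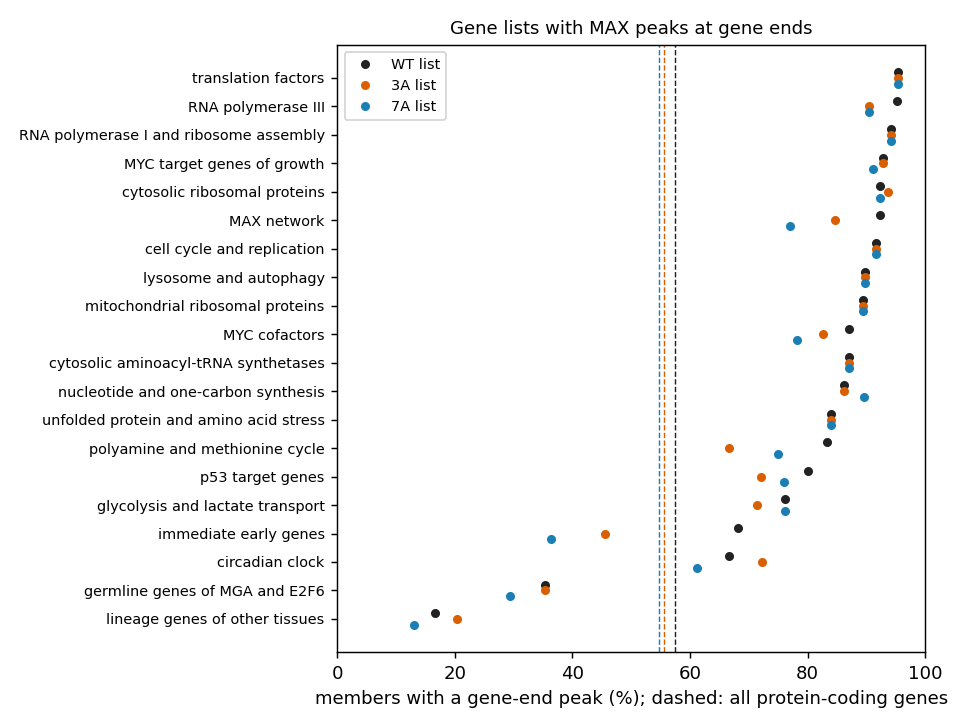
Share of the members of each of the 20 gene lists with a MAX peak within 1000 bp of a gene end (horizontal axis, %), by peak list; dashed lines mark all protein-coding genes, at 57.4% for WT, 55.5% for 3A and 54.7% for 7A. Translation factors and ribosome assembly genes lie above 94.0% in all 3 lists, and lineage genes of other tissues below 21.0%.

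Genes of other lineages and of the germline were mostly without gene-end peaks. Of 54 lineage genes of other tissues, 9 had a WT peak (odds ratio 0.148, exact adjusted p = 8.97e-09), 11 a 3A peak and 7 a 7A peak, with GRIN1 (40.8), SNAP25, APOA1 and SFTPC in front. Of the 34 genes listed as germline genes of MGA and E2F6, 12 had a WT peak (odds ratio 0.404, exact adjusted p = 0.0184), 12 a 3A peak and 10 a 7A peak. This depletion did not pass in WT with the background of genes with a peak within 10000 bp (exact adjusted p = 0.0699) or with whole gene bodies (exact adjusted p = 0.136), nor in 3A with these (0.120 and 0.153) or with 2500 bp (0.0580). HSF2BP, which shares its peak with RRP1B, ZCWPW1 (64.3), STAG3 and SMC3 were the strongest of the listed genes.

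Within the MAX network, 12 of 13 genes had a WT peak (odds ratio 8.90, exact adjusted p = 0.0147), 11 a 3A peak (exact adjusted p = 0.0637) and 10 a 7A peak (exact adjusted p = 0.180). The WT call ended with the background of genes with a peak within 10000 bp (exact adjusted p = 0.429), and 3A passed with lists of equal length (0.0360) and with 2500 bp (0.0252). With whole gene bodies the network passed in 3A (13 of 13, exact adjusted p = 0.00921) and in 7A (12 of 13, exact adjusted p = 0.0494). In WT the fold enrichments were 74.3 at MXD3, 68.3 at MLXIP, 60.3 at MXD1, 52.98 at MGA, 29.4 at MAX itself, 26.9 at MNT, 24.8 at MXD4, 18.9 at MLX, 9.80 at MYCN, 8.48 at MYC, 4.75 at MLXIPL and 4.70 at MYCL. MYC had no gene-end peak in the 7A list, MLXIPL none in either mutant list, and MXI1 none in any, though one in all 3 with 2500 bp.

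The fifth comparison asked whether genes with a WT gene-end peak also had a gene-end peak in the mutant lists. Such genes are called kept below, also where the mutant peak lies at another position or at the other end of the gene. Of the 11471 genes with a WT gene-end peak, 94.6% (94.1 to 94.97) had one in 3A and 93.7% (93.2 to 94.1) in 7A, and 456 had one in neither. Immediate early genes, which respond within minutes to growth signals, stood apart: of 15 with a WT peak 9 had one in 3A and 8 in 7A, at percentiles 0.005 and 0 of 10000 gene sets matched on WT fold enrichment. Of the 6 with no peak in either mutant list, CCN1 (24.6), DUSP1 (19.5), FOS (19.5) and KLF6 (18.9) were the strongest, whereas JUNB (84.3), JUND (41.9) and NR4A2 (19.6) had peaks in all 3 lists. By enrichment alone this group did not pass in WT (15 of 22, odds ratio 1.59, exact adjusted p = 0.411). It did with 2500 bp (20 of 22, exact adjusted p = 0.00837), and with the background of genes with a peak within 10000 bp it was depleted in 3A (exact adjusted p = 0.0206) and 7A (exact adjusted p = 0.00159). With summits up to 2500 bp from a gene end, 17 of 20 had a 3A peak (percentile 4.5) and 15 a 7A peak (percentile 0.18), and FOS and DUSP1 had one in all 3 lists.

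All 49 ribosome assembly genes, 41 translation factors, 20 aminoacyl-tRNA synthetases, 33 cell cycle genes, 35 lysosome genes and 21 stress genes with a WT peak had one in both mutant lists, at percentiles between 69.6 and 87.8. A group that kept every member could not rank higher, since matched sets that also kept all of theirs count as ties. Cytosolic ribosomal protein genes kept 72 of 72 in 3A and 70 in 7A (percentile 17.6), mitochondrial ones 67 of 68 in each, and RNA polymerase III genes 19 of 20 in each (percentiles 27.5 and 31.8). The polyamine and methionine cycle kept 8 of 10 in 3A (percentile 0.575), with OAZ1 (28.5), an inhibitor of ornithine decarboxylase, in neither mutant list, and 9 of 10 in 7A (percentile 9.64). In 3A it kept 10 of 11 with 2500 bp (percentile 6.92), where OAZ1 had a peak in all 3 lists, and 7 of 10 with lists of equal length (percentile 0.02). Lineage genes of other tissues kept 9 of 9 in 3A and 7 in 7A (percentile 4.33), and in 7A 9 of 13 with 2500 bp (percentile 0.46) and 7 of 8 with lists of equal length (percentile 13.4). Germline genes kept 11 of 12 in 3A and 10 in 7A (percentile 6.54), with lists of equal length 10 of 10 in each, and with 2500 bp 14 and 13 of 15 (percentiles 37.6 and 14.4). MYC cofactors kept 18 of 20 in each (percentiles 10.9 and 13.4), with lists of equal length 17 in 3A (percentile 2.89) and 18 in 7A (percentile 8.55), and with 2500 bp 20 of 21 in each (percentiles 29.5 and 34.8). Percentiles of the remaining groups, the MYC targets, the MAX network, nucleotide synthesis, glycolysis, p53 targets and the circadian clock, lay between 10.2 and 79.5. Members of other groups with a WT peak alone were PFKP (22.8), EP300 (12.0), KAT2A (11.2), BRF1 (10.7), CIART (9.81), MRPL35 (9.50), RNF212 (7.39), MLXIPL (4.75) and CDKN1A (4.31), the last an inhibitor of the cell cycle. With 2500 bp PFKP, EP300 and BRF1 had a peak in all 3 lists and CDKN1A in WT and 7A, and with lists of equal length RNF212 and MLXIPL had none in any. The lists offer 40 such percentiles, of which some lie near either end by chance.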

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

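On contigs other than chromosomes 1 to 22 and X, the WT list held 5 peaks, the 3A list 3 and the 7A list 2. They entered the overlap of the lists, and no comparison with genes used them.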

How the results depend on the processing

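No paired analysis was possible because the libraries share replicate numbers in the labels while the peak lists carry none, and leaving out a replicate was not possible for the same reason. The planned E-box alternatives were not run, for want of a genome sequence. Peak numbers stayed within 1.5 times under every alternative run. Where a value below moved and its setting does not itself add or remove peaks, the cause was not tested. The depth of the libraries, which limits weak peaks, is not given in the lists. Ratios of mutant to WT depth were estimated from the recovered coverage. For 3A they were 0.625 by background and 0.631 by treatment, and for 7A 0.875 and 0.609.

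Asking for 50% of both peaks gave 68.8% of WT peaks with a 3A partner, 65.5% with a 7A partner and 26.2% with neither, 83.3% of 3A peaks with a 7A partner and 90.4% the reverse. Summits within 100 bp gave 65.1%, 60.3%, 29.7%, 79.2% and 85.9% in that order. Lists of equal length gave 82.6%, 81.9%, 13.6%, 90.2% and 89.4%, and the strongest 5000 peaks 74.7%, 71.6%, 20.9%, 84.4% and 84.2%. In the last setting a partner outside the strongest 5000 of its own list was not counted. The gene-end shares of WT, 3A, 7A and WT peaks with no partner were 25.6%, 31.8%, 33.9% and 5.28% with a window of 500 bp, 36.8%, 43.4%, 45.1% and 14.5% with 2500 bp, and 64.6%, 68.8%, 69.8% and 51.02% with whole gene bodies, a setting chosen after the data were seen. WT stayed below both mutants in each.

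With genes that had a peak within 10000 bp as background, 7 gene lists were enriched in WT and 7 in 3A, and 1 was depleted in WT. With whole gene bodies 1 was depleted in WT and 1 in 3A, and with 2500 bp 1 in 3A. With lists of equal length, 95.7% of genes with a WT gene-end peak had a 3A one and 96.6% a 7A one.

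For single gene lists the call was unaltered in 251 comparisons with an alternative, ended in 23, of which 18 came with the background of genes with a peak within 10000 bp, and was gained in 26. Shares of single gene lists kept in a mutant lay inside their interval in 69 comparisons and outside in 11, and shares of mutant peaks on WT peaks inside in 2 and outside in 8. The number of peak lists with a gene-end peak of a named gene was unaltered in 445 comparisons and differed in 17. Differences in rank, an analysis added after the data were seen, were unaltered in 37 comparisons, lost in 2 (cell cycle, polyamine cycle) and gained in 1 (glycolysis) when −log10 p or treatment coverage replaced fold enrichment.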

Other observations

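The tests at percentile 10, with depth from background or treatment, those on as many weakest peaks as have no partner, and the ranking of gene lists across peak lists were chosen only after the data were seen.

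Ranked by fold enrichment within each list among the 10575 genes with gene-end peaks in all 3, cytosolic ribosomal protein genes had a median percentile of 88.6 in WT, 89.2 in 3A and 71.3 in 7A. RNA polymerase I and ribosome assembly genes had 86.0, 83.1 and 76.1. Cell cycle and replication genes went the other way, with 54.5, 64.3 and 69.6, and 6 of 33 ranked higher in WT than in the mean of the mutants (percentile 1.58 of matched gene sets; by treatment coverage 5.71; against 3A alone 10.7 and 7A alone 3.41). Across the 23007 regions common to all lists, which are not independent replicates, Spearman's rho of the fold enrichment was 0.690 for WT and 3A, 0.687 for WT and 7A and 0.734 for 3A and 7A, and that of treatment coverage, where solved (20856 regions), was 0.848, 0.830 and 0.936 in that order. The median background coverage was 12.0 in WT, 8.06 in 3A and 11.9 in 7A, and on chromosome 22 it was 20, 12.7 and 18.2. These are on unlike footings, since the treatment appeared scaled down in WT and 3A (steps of 0.696 and 0.689) and the background in 7A (0.932).

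The WT list held more peaks than the 3A list, for which shallower libraries behind the 3A list are a candidate explanation. After thinning WT coverage to the background of the 3A list, 99.9% of the WT peaks with no 3A partner reached its lowest −log10 p, but that test could hardly fail, since percentile 1 of the 3A list (15.9) lies far above its lowest value (7.203). Its percentile 10 (27.5) was reached by 79.0% before thinning and by 48.8% (47.8 to 49.9) after. With depth taken from the treatment it was 49.7% (48.6 to 50.8). Both lay under the bound of 50%, the second with an interval past it. Of the WT peaks with a 3A partner, 96.3% reached it before thinning and 87.1% after thinning by the background. Some 3A peaks lie below percentile 10 of their own list, so that missing it does not mean that a peak would go uncalled. The test therefore does not decide, and depth stays open. Peaks close to the calling threshold are another candidate. Of the WT peaks with no 3A partner, 45.5% were in the weakest 20%, where 77.1% was the most possible. Among as many weakest peaks as have no partner were 56.0%, against a bound of 80%. These values rank peaks by WT strength, while a partner is missing where the 3A signal falls below its own threshold. They therefore do not decide how much the threshold accounts for. An effect of the 3A mutation stays open and untested, with 1 list per form.

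The WT list also held more peaks than the 7A list. After thinning, 99.99% of the WT peaks with no 7A partner reached the lowest −log10 p of the 7A list, in a test as weak as that for 3A. Its percentile 10 was reached by 69.0% before thinning and by 60.3% after thinning by the background. With depth taken from the treatment it was 37.9%. These lay on opposite sides of the bound of 50% but are on unlike footings. The recovered WT treatment appeared already scaled down, so that the treatment ratio can take off too much. Some 7A peaks also lie below percentile 10 of their own list, so that missing it does not mean that a peak would go uncalled. Depth therefore stays open. In the weakest 20% lay 43.1% of them, where 66.4% was the most possible, and 60.4% were among as many weakest peaks, below the bound of 80%. For the same reason as in 3A, these values do not decide how much the threshold accounts for. Unlike scaling of the libraries and an effect of the 7A mutation stay open.

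The mean rank of MYC target genes of growth was 1.40 percentile points higher in WT than in the mutants, with 26 of 51 genes higher. The mean difference was 2.52 points over 7A (29 of 51) and only 0.274 over 3A (25 of 51). Among matched gene sets these lay at percentiles 99.9, 100 and 99.96, in that order. Matched sets can have negative differences: aminoacyl-tRNA synthetases, at −5.60 points over 3A, lay at percentile 51.5. A high percentile alone therefore does not show a higher rank in WT. Chance low background in WT is argued against, since ranks by treatment coverage gave percentile 100, with a mean difference of 5.08 points (34 of 49 genes higher). Ranks by background coverage gave 99.99, with a mean difference of 11.1 points, but a higher background lowers the fold enrichment and extra copies raise treatment and background alike, so this test is no evidence for copy number differences and leaves them undecided. Ribosome assembly genes, which share no member with this list, also ranked higher (percentile 100; by 4.71 points over 3A and 8.80 over 7A). Other lists were mixed. Against the mean of the mutants, cytosolic ribosomal protein genes ranked 9.86 points higher in WT (percentile 100). Aminoacyl-tRNA synthetases lay at −1.10 points (percentile 72.6), and cell cycle genes at −9.95 (percentile 1.58). MYC targets ranked almost level in WT and 3A by fold enrichment only. By −log10 p they ranked 2.47 points higher in WT than in 3A (30 of 51 genes). By treatment coverage they ranked 4.05 points higher (34 of 49 genes). The lists hold MAX peaks and do not separate Dox from no Dox. Wild-type MYC at genes of cell growth therefore stays open. With 1 list per form the explanations left open cannot be separated further.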
